A study of Drosophila melanogaster with 3 samples.

How the data were processed

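Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of 0 to 24 hours that carried a transgene for Doc3 fused to enhanced green fluorescent protein (eGFP). The fusion protein was pulled down with an anti-GFP antibody. Per the labels, chromatin was sheared by sonication to a range of 200 to 800, and 3 biological replicates were made. The replicate numbers used here are those of the labels. All samples form a single group. A possible control experiment is named in the labels but was not analysed here, so no comparison with a mock or input sample was made.

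The deposited files used were peak lists on the dm6 genome build, per the labels. For each replicate there was a ranked list of regions and a thresholded list, and for the whole series there were 4 thresholded lists, of which the authors marked 1 as conservative. Per the file headers, the lists were derived from alignments on dm6. The aligner, the peak caller and their versions are not given in the sources used here, and neither are the replicates that each series-level list compared or pooled. The authors' signal value of each region is the strength their peak caller gave it, on a scale that is not stated and that differs between lists made from different reads. It was therefore used only to rank, filter or describe peaks within a list. The deposited score of each region is a scaled irreproducible discovery rate (IDR), and all thresholded lists held only scores that stand for an IDR of 0.01 or less under the usual scaling. Sequencing depth is unknown, since the lists give no read numbers. Series-level ranked lists were not used here, because 2 unnamed inputs in them cannot be tied to samples.

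Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes and transcription start sites (TSSs) came from Ensembl release 115, whose annotation 6.54 describes the same genome release 6 as dm6. The main analyses used the 6 chromosome sequences X, 2L, 2R, 3L, 3R and 4, except that sizes and overlaps of the replicate lists count all their peaks. Peaks overlapped when they shared at least 1 bp. Overlaps and genomic positions were compared with 1000 random placements of the peaks on their own chromosomes. A summit within 500 bp of any annotated TSS was called promoter, and the remaining summits were assigned in the order coding exon, 5' UTR, 3' UTR, intron and intergenic. Exons of non-coding genes were kept as a class of their own, a choice made after the annotation was examined. Peaks were assigned to the protein-coding gene with the nearest TSS, with ties settled alphabetically.

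Sequence motifs were sought on both strands within 50 bp of each summit. The same search was made in a window of equal length centred 500 bp to the left or right, chosen at random, and an exact two-sided sign test compared the windows of each peak. P-values were adjusted by the Benjamini-Hochberg method over 21 motifs, and separately over 2080 6-mers collapsed with their reverse complements. For 31 gene lists, the number of members with a peak was compared with 100000 random lists of genes matched on decile of territory, the length of genome nearer to a gene's TSSs than to those of any other gene. That permutation test was two-sided, with adjustment over the 31 lists. Of 514 symbols written into the lists, 506 were found in the annotation, and 4 of the lists were drawn by symbol pattern instead. Signal of peaks with and without the T-box motif was compared by a two-sided permutation test of medians with 100000 resamples. Shares carry 95% Wilson intervals, which cover counting error only. Signal of a conservative peak in a replicate was the highest value of the overlapping regions in that replicate's ranked list.

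The sign test and the gene list test were checked on simulated data. With a motif implanted in 20% of 2000 windows, the recovered difference was 18.5 percentage points, and with nothing implanted 2.5% of 200 runs gave p under 0.05. Of 300 unchanged lists, 3% gave p under 0.05, and 96% of 100 lists of 25 genes with 40% of members added were recovered at unadjusted p under 0.05. Shorter lists, smaller effects and adjusted p-values were not simulated. The checks therefore do not show how often the tests below would find a weak excess.

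The main tests, gene lists, motifs and most alternatives were fixed before the data were examined. The genes named are the 3 Dorsocross genes, the nearest genes of the 25 conservative peaks with the highest signal (except 1, which is not reported here), and for each list described up to 4 members with the highest signal and up to 2 members without a peak, first in the alphabet. Counts of 5 or fewer are named in full. The alternatives were a stricter list, the other series-level lists, leaving out each replicate, other overlap rules, promoter distances, summit definitions, motif windows, motif spellings and backgrounds, and other rules to tie peaks to genes. For promoters, motifs, signal and gene lists, leaving out a replicate meant keeping the conservative peaks overlapped by the thresholded lists of both other replicates. The conservative set was not made anew, so these settings are stricter filters on it. Merging of overlapping peaks, a count on the main chromosomes, coding TSSs alone, the alternatives for rank correlations, the masking of Motif 1 and every alternative for sequences other than the T-box ones were added after the data were examined.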

Results

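Doc3 is a T-box transcription factor, encoded together with Doc1 and Doc2 at the Dorsocross locus and known for roles in the amnioserosa and the developing heart. Where the eGFP-tagged protein was recovered on chromatin in whole embryos was measured by anti-GFP ChIP-seq in 3 biological replicates of 1 group. The thresholded lists held 1774 peaks in replicate 1, 2486 in replicate 2 and 1812 in replicate 3, a mean of 2024 ± 401 (SD, n = 3). They covered 559 kb, 838 kb and 613 kb, with median widths of 364, 404 and 380 bp. The ranked lists, which also hold weak regions, had 30159, 59389 and 141211 entries. The conservative set of the whole series, on which the regional results rest, held 2793 peaks with a median width of 484 bp. Some of its peaks overlap each other, and merging them left 2270 separate regions covering 1050 kb. Of the 279 weakest conservative peaks, 273 (97.8%, interval 95.4 to 99.0%) overlapped a stronger peak of the same set, against 16 of the 1396 strongest (1.15%).

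The question of how far the replicates found the same regions was addressed first. Strong promoter peaks such as those of mtSSB, Rpn6 and RpL32 were found in each replicate, and all 25 of the strongest conservative peaks were overlapped in all 3 lists. Replicates 1 and 2 shared 88.2% of the smaller list (interval 86.6 to 89.6%), replicates 2 and 3 shared 88.1% (86.6 to 89.5%), and replicates 1 and 3 shared 78.5% (76.5 to 80.3%). Random placements gave 0.907 to 1.30% on average, and none of 1000 placements reached the observed overlap (one-sided permutation p = 0.001, the smallest it can give, for each pair). The placements were spread over whole chromosomes, so they understate the overlap of unrelated lists that both gather at promoters. Across the whole conservative set, 1498 of 2793 peaks (53.6%, interval 51.8 to 55.5%) were overlapped in all 3 replicates, 476 in exactly 2, 431 in 1 and 388 in none. The set was derived from the same 3 samples, so this share is described only. In 4 groups of 698 or 699 peaks, from the strongest down, the share in all 3 was 97.4, 70.5, 13.9 and 32.8%, and 64.8% of the weakest group overlapped a stronger peak. The rule for overlap mattered: with 50% of both peaks required, 31.0% of the set was shared by all 3. Across regions, which are not independent replicates, Spearman's rank correlation of signal was 0.851 for replicates 1 and 2, 0.842 for 1 and 3, and 0.881 for 2 and 3.

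The recovered regions lay at the start of genes. Of the 2793 conservative summits, 2591 (92.8%, interval 91.7 to 93.7%) lay within 500 bp of an annotated TSS, 6.82 times the 13.6% of random placements. The median distance to the nearest protein-coding TSS was 80 bp, with quartiles of 35 and 154 bp. Within 500 bp, 1774 summits lay upstream of the nearest coding TSS and 760 lay at it or downstream. Introns held 95 summits (3.40% against 39.5% at random), intergenic sequence 70 (2.51% against 27.2%), coding exons 17 (0.609% against 13.9%), 3' UTRs 13 (0.465% against 4.43%) and 5' UTRs outside promoters 6 (0.215% against 0.607%). A single summit fell in an exon of a non-coding gene (0.0358% against 0.820%). Each class differed from random placement, with two-sided permutation adjusted p = 0.00799 for 5' UTRs and 0.00233 for each other class. The classes exclude each other and promoter came first, so the promoter excess by itself lowers the shares of the others. Their p-values therefore do not show that these classes were avoided. How summits outside promoters spread over the other classes was not tested. Only 57 summits (2.04%) were over 5 kb from a coding TSS. Peaks were assigned to 2274 of 13945 coding genes (16.3%), and 1122 peaks had TSSs of at least 2 coding genes within 500 bp, so the gene assigned to such a peak is not the only candidate.

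**Figure D1:**
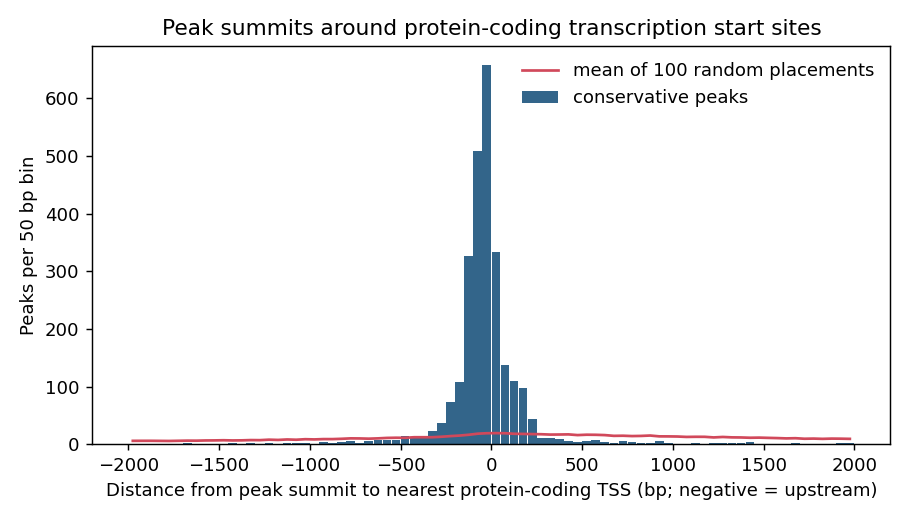
Number of conservative peaks in 50 bp bins of distance from the summit to the nearest protein-coding TSS (x axis in bp, negative upstream), with the mean of 100 random placements as a line. The bars gather just upstream of the TSS, at a median absolute distance of 80 bp.

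The strongest peaks lay at promoters. The highest signal value, 1793, was found 43 bp upstream of mtSSB, which encodes the mitochondrial single-stranded DNA-binding protein, on 3R from 16205091 to 16205507. Other strong peaks lay at Rpn6, a subunit of the proteasome lid (1330.1, 2R from 14752157 to 14752608), Jwa (1205, 2L from 18705617 to 18706007) and RpL32, a protein of the large ribosomal subunit (1181, 3R from 30046055 to 30046475). Further peaks among the 25 strongest lay at MESK2, Sry-alpha, CG14441, Capr, PGAP3, CG1965, CG11857, Mic26-27, Mppe, Oatp30B, Creld, CG11755, CG8613, Dpit47, Gp150, Hacl, XNP, Coq7, Pym and MED7, a subunit of the Mediator complex, with signal values down to 875. All of the 25 summits lay within 158 bp of a coding TSS. Of the 25, 12 had TSSs of at least 2 coding genes within 500 bp, Rpn6, RpL32 and MED7 among them, and Sry-alpha shares its start with Sry-beta.

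Whether the T-box binding sequence marks the summits was tested next. GGTGTGA, the core recognised by T-box proteins, lay within 50 bp of 32 of 2793 summits (1.15%, interval 0.813 to 1.61%) and in 22 flank windows (0.788%, interval 0.521 to 1.19%). The difference of 0.358 percentage points did not pass the exact sign test (p = 0.220, adjusted p = 0.421). The longer AGGTGTGA occurred at 9 summits and 4 flanks (exact sign test, adjusted p = 0.451), and the shorter GGTGTG at 105 summits and 102 flanks (adjusted p = 0.888). The degenerate AGGTGTNR occurred at 38 summits and 45 flanks (exact sign test, adjusted p = 0.617). Peaks with GGTGTGA had a median signal of 159, against 171 for the 2761 others (difference -11.7, permutation p = 0.718). None of the 25 strongest peaks held GGTGTGA within 50 bp of the summit, but at a share of 1.15% so few peaks cannot show a lack.

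Elements of core promoters were frequent instead. TATCGATA, the DNA replication-related element read by DREF, lay at 513 summits (18.4%, interval 17.0 to 19.8%) and in 10 flanks (0.358%), a 51.3-fold higher share (exact sign test, adjusted p = 3.07e-138). In the same 4 groups from the strongest peaks down, the share was 26.5, 24.8, 18.2 and 4.01%, and most peaks of the last group overlap a stronger one. Motif 1, GGTCACACT, lay at 68 summits (2.43%) and in 7 flanks (0.251%; exact sign test, adjusted p = 1.23e-12), with shares of 1.29, 4.15, 2.58 and 1.72% in these groups. In the search over 2080 6-mers, the first ranks were taken by TATCGA (1129 summits, 40.4%, against 100 flanks, 3.58%; exact sign test, adjusted p = 7.12e-240), ATCGAT (1022 against 95) and CGATAG (867 against 60), all parts or near neighbours of TATCGATA. GGTGTG ranked 743. GTGTGA, which is part of GGTGTGA and of Motif 1, was among the 319 6-mers that were more frequent at summits past the threshold (193 summits against 118 flanks; exact sign test, adjusted p = 9.04e-05), and with copies of Motif 1 masked it was left at 131 summits and 111 flanks (exact sign test, p = 0.210). The Snail E-box CAGGTG (87 summits, 164 flanks), the Twist E-box CAYATG (134 and 206) and CACACACA (27 and 87) were less frequent at summits than in flanks, with adjusted p = 4.66e-06, 0.000332 and 1.07e-07 in the exact sign test. Against shuffled summit windows with the same dinucleotides these 3 were not lower past the threshold. The CA repeat was then higher by 0.644 percentage points, which passed (exact sign test, adjusted p = 0.0104). The other 12 motifs searched, GAGA, Zelda, Tinman, GATA, homeodomain, Smad, STAT, AP-1, Su(H), Grainyhead, Caudal and Scalloped sequences, did not pass the test.

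**Figure D2:**
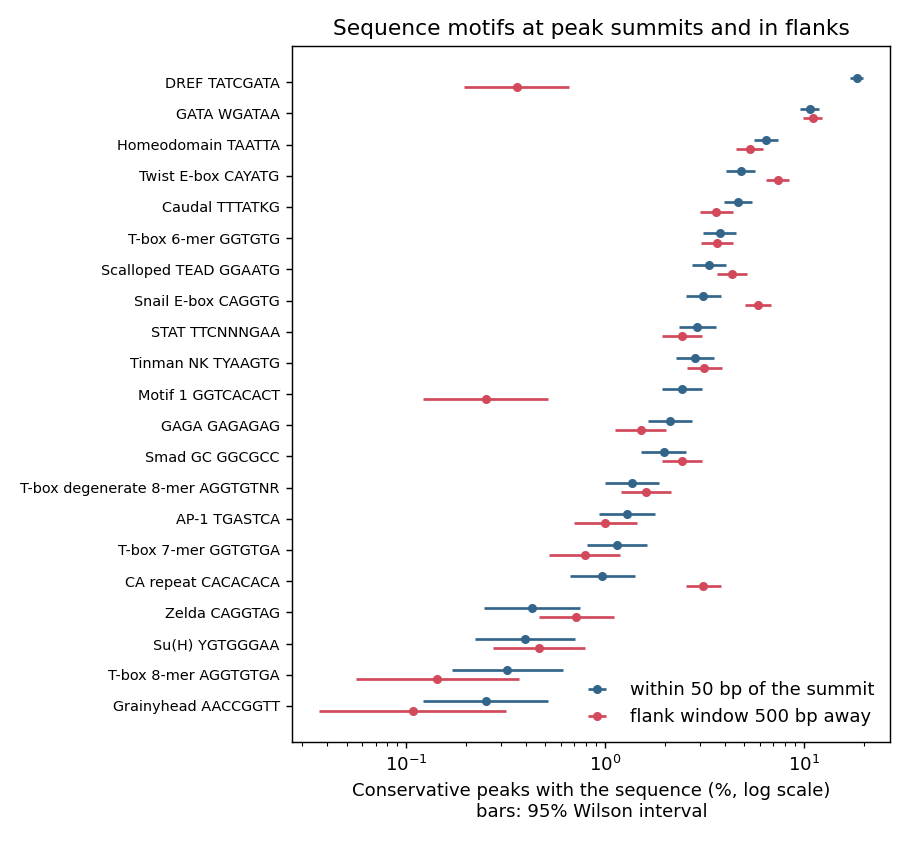
Share of conservative peaks (x axis, %, log scale) that hold each of 21 sequences within 50 bp of the summit or in a flank window 500 bp away, with 95% Wilson intervals. TATCGATA at 18.4% against 0.358% and Motif 1 at 2.43% against 0.251% stand apart, while the intervals of the T-box sequences overlap.

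The sequence around some of the strongest summits shows these elements. At Creld, on 2L from 102181 to 102581, the 51 bases centred on the summit read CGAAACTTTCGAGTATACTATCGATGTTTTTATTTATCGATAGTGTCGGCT and hold TATCGATA. At mtSSB they read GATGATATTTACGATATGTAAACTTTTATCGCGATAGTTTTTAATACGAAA, with no full copy. Among the 25 strongest peaks, 2 held TATCGATA within 50 bp, Creld and Pym, and 11 held it within 250 bp. In the whole set, 1012 peaks held it within 250 bp, at a median of 46 bp from the summit to its centre, and 53.5% of these had the centre of the nearest copy within 50 bp, where an even spread would put 20.4%.

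The gene lists asked whether groups of genes with known roles carried peaks more or less often than genes of like territory, where a gene had a peak if it was the nearest gene of one. Genes for cytosolic ribosomal proteins, which build the ribosome in every cell, carried peaks most clearly: 29 of 79 (36.7%) against 12.96 expected (adjusted p = 0.000827, permutation of matched lists). RpL32, RpS2, RpS7 and RpL26 had the highest signal values (1181, 741, 681 and 616), and RpL10 and RpL13A were without a peak. The call was lost among the 1544 conservative peaks overlapped in both replicates 1 and 3 (14 against 7.65 expected, permutation adjusted p = 0.224). It was also lost among the 1729 overlapped in both replicates 1 and 2 (17 against 8.52, permutation adjusted p = 0.0625). These are smaller parts of the same set, which was not called anew without a replicate. For mitochondrial ribosomal proteins, 18 of 73 members had a peak against 11.3 expected (permutation adjusted p = 0.271), led by mRpL4, mRpL42, mRpL10 and mRpS17. This list passed the threshold in 2 of the other series-level lists, with 27 members (adjusted p = 0.00248) and 19 members (adjusted p = 0.0451) in the permutation test. Any peak within 500 bp of the 5'-most TSS was also counted, even if nearer to another gene. By this rule, 37 of 79 cytosolic (46.8%) and 27 of 73 mitochondrial members (37.0%) had one, against 2859 of all 13945 coding genes. Glycolysis and TCA cycle enzymes, with 5 of 25 members, did not pass the permutation test (adjusted p = 1): Eno had the highest value (758), followed by Scsalpha1, Idh3b, Ogdh and PyK.

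Lists of receptors, cuticle proteins and histones carried fewer peaks than matched genes. None of 119 odorant and gustatory receptor genes had a peak, against 19.8 expected, and none of 118 cuticle protein genes did, against 19.9 expected (adjusted p = 0.00031 for each, from the smallest p the permutations can give). Histone genes had 4 members of 115 against 16.3 expected (permutation adjusted p = 0.00139). Those 4, His3.3A, His4r, His3.3B and His2Av, are replacement-type genes outside the repeated histone cluster, whose copies are hard to tell apart by short reads. The low count of this list can therefore not be read as avoidance of histone genes. Chorion and vitelline membrane genes (0 of 14, 2.36 expected) and neuronal differentiation genes (0 of 17, 2.55 expected, ChAT and Csp among them) did not pass the permutation test, with adjusted p = 0.513 and 0.482. The chorion list passed when whole gene bodies were used (0 against 5.26 expected, permutation adjusted p = 0.0161).

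No list of the tissues in which Doc3 is known to act stood apart from matched genes. Of 28 regulators of heart and dorsal mesoderm, 5 had a peak against 4.0 expected (permutation adjusted p = 1). In the smaller sets without replicate 1, 2 and 3, the count was 1, 1 and 2, against 2.38, 2.10 and 2.42 expected. The peaks at tin, the cardiac NK factor (263), Mef2 (202) and eve (98.1) lay within 221 bp of a TSS, while that of Ubx (94.4) lay 31484 bp downstream of its nearest TSS, and that of zfh1 (55.9) lay 6216 bp downstream. Heart differentiation genes had 2 of 18 (robo1 and Dg), against 2.75 expected. Amnioserosa and dorsal ectoderm genes had 4 of 27 (msn, tok, hep and kay), against 3.98 expected, the peak of msn 6266 bp downstream of a TSS, and Ance and C15 were without. T-box genes had 1 of 8, org-1, whose peak lay 2491 bp downstream of a TSS with a signal of 393. Signalling genes did not pass either: the Dpp pathway had 6 of 24, with dlp, tok, tkv and Mad (262, 237, 218 and 93.0), against 3.65 expected (permutation adjusted p = 0.700), and passed with 13 members when whole gene bodies were used (adjusted p = 0.0390) and with 9 in another series-level list (adjusted p = 0.0451). The counts were 6 of 22 for Wingless (fz3, pan, Apc and pygo, 3.33 expected) and 6 of 16 for Notch (mam, Su(H), fng and E(spl)m3-HLH, 2.62 expected). Hedgehog genes had 5 of 12 (boi, dlp, slmb, ihog and ptc, 1.85 expected) and JAK/STAT genes 3 of 9 (Ptp61F, Stat92E and hop, 1.43 expected). EGFR and FGF genes had 4 of 22 (ru, sty, spi and S, 3.11 expected). Each of these counts lay above its expectation, but none passed the permutation test, with adjusted p from 0.271 to 1.

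**Figure D3:**
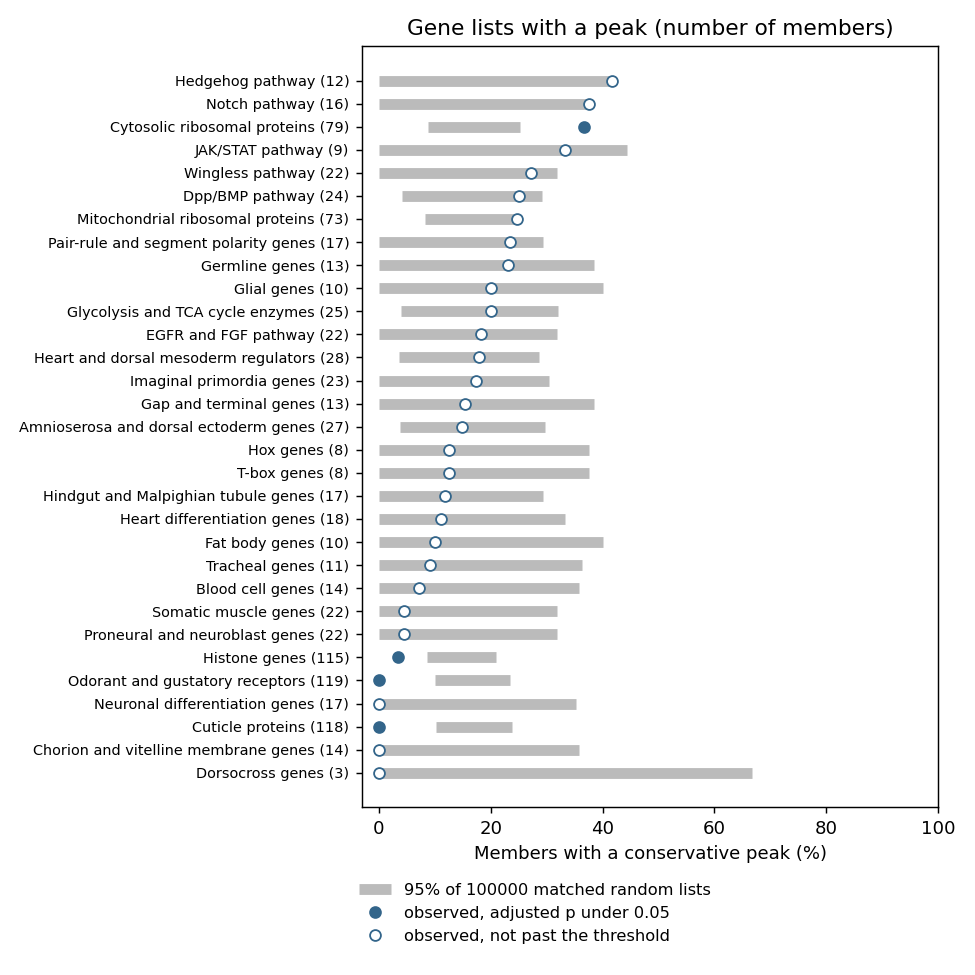
Share of the members of 31 gene lists with a conservative peak (points, x axis in %), with the central 95% of 100000 random lists matched on territory as bars and the number of members in brackets. Cytosolic ribosomal proteins lie above the bar at 36.7%, and receptors, cuticle proteins and histones lie below it.

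Other developmental lists did not pass the permutation test, with adjusted p from 0.700 to 1. These were gap and terminal genes (2 of 13, ems and btd, 1.82 expected), pair-rule and segment polarity genes (4 of 17, sob, drm, eve and hry, 2.36 expected), Hox genes (1 of 8, Ubx, 1.05 expected), hindgut and Malpighian tubule genes (2 of 17, ems and drm, 2.35 expected) and imaginal primordia genes (4 of 23, btd, exd, bab1 and Dll, 3.09 expected). Proneural and neuroblast genes had 1 of 22 (grh, 3.22 expected), glial genes 2 of 10 (loco and nrv2, 1.69 expected), somatic muscle genes 1 of 22 (Mef2, 3.25 expected), blood cell genes 1 of 14 (Pvr, 2.25 expected), tracheal genes 1 of 11 (grh, 1.57 expected), fat body genes 1 of 10 (Desat1, 1.70 expected) and germline genes 3 of 13 (tud, gcl and bgcn, 2.17 expected). The peaks assigned to ems, bab1, drm and btd lay 20180, 17583, 16174 and 13834 bp downstream of a TSS, and with a limit of 5 kb the gap, hindgut and Hox lists had 0 members each.

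The Dorsocross locus was examined for peaks at the factor's own genes. Doc3 (3L from 9005196 to 9007249), Doc2 (3L from 9012686 to 9019246) and Doc1 (3L from 9041375 to 9045042) had no conservative peak and no thresholded peak in any replicate. The nearest conservative peak, 7.17 kb from the locus, was assigned to smg (3L from 8997781 to 8998264, signal 156). The ranked lists held weak regions between the ends of the 3 genes, 13 in replicate 1, 24 in replicate 2 and 49 in replicate 3. The strongest of them had signal values of 19.7, 37.2 and 42.7, where the medians at conservative peaks were 43.7, 92.1 and 75.9. The longest series-level list, of 3513 peaks, had 1 peak there, from 9010445 to 9010928, with its summit 849 bp upstream of CG5194.

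**Figure D4:**
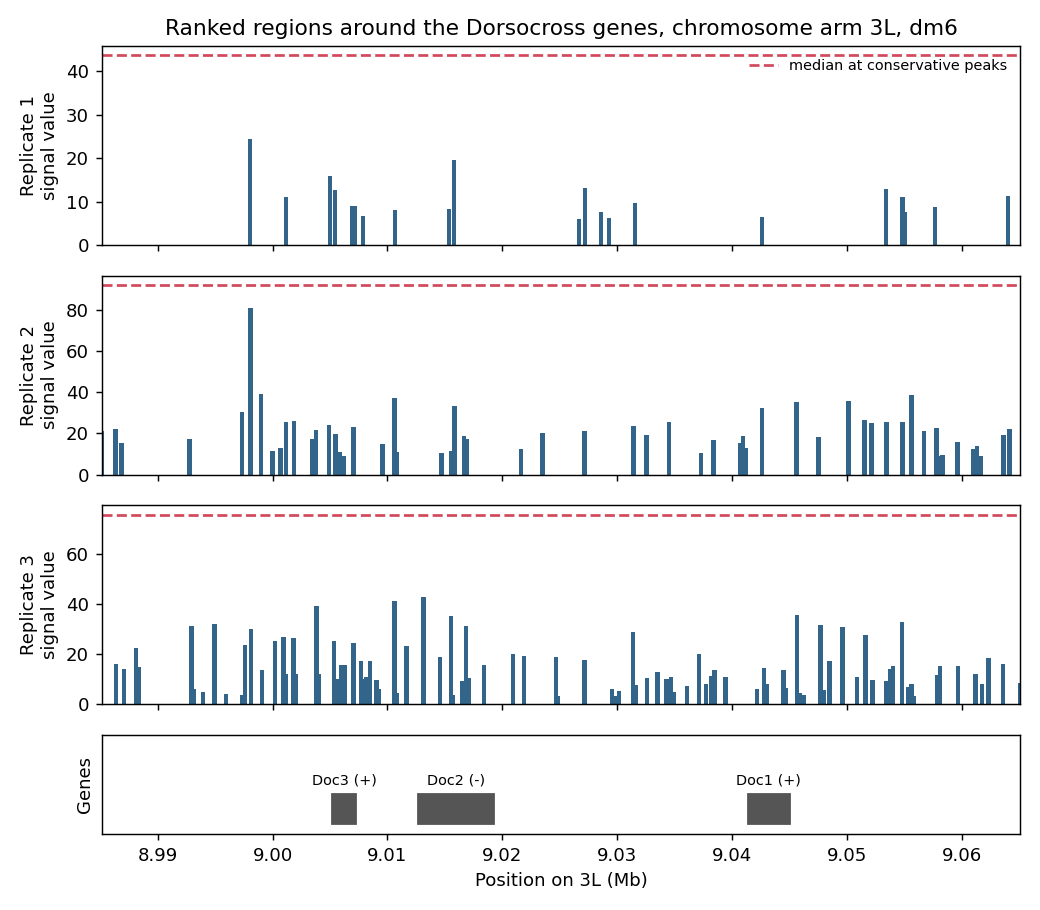
Signal value (y axis, authors' scale, separate for each replicate) of the ranked regions in 80 kb around the Dorsocross genes (x axis, position on 3L in Mb), with the median at conservative peaks as a dashed line and gene spans below. The strongest regions between the genes reach 19.7, 37.2 and 42.7, all under the dashed lines.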

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

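Peaks outside the main chromosomes count in the sizes and overlaps of the replicate lists but were in no comparison of positions, motifs or genes, and with no control sample they were set against the 3 that a count of 0 allows, a limit for independent counts, which overlapping peaks are not. The thresholded list of replicate 1 held 12 peaks on the mitochondrial genome, which merge into 7 regions, with a highest signal of 6429.8 against 341 on the main chromosomes. Neither the thresholded nor the ranked lists of replicates 2 and 3 held any. The thresholded list of replicate 3 held 10 peaks on unplaced scaffolds, against 1 in replicate 1 and 0 in replicate 2.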

How the results depend on the processing

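The alternatives with merged peaks, main chromosomes alone or coding TSSs alone, and those of the rank correlations and of sequences other than the T-box ones, were chosen after the data were examined. For promoters, motifs, signal and gene lists, settings without 1 replicate kept the conservative peaks overlapped in both other replicates, with no new peak call. The pairwise overlap of replicates, the promoter share (83.8 to 96.4% over all alternatives) and the excess of TATCGATA, TATCGA and Motif 1 kept their direction and passed the test in each alternative run. GGTGTGA stayed above its background in each alternative, by 0.194 to 0.716 percentage points, but none brought it past the threshold (exact sign test, adjusted p 0.0833 to 0.838). These alternatives share peaks, so they are not separate tests. Where neither setting passed, directions of gene lists were not compared. Lists above expectation numbered 1, but 2 with the 3513-peak list, 3 with the 2456-peak list, 2 with gene bodies plus 2 kb, and 0 to 1 without 1 replicate; lists below expectation numbered 3 or 4. The rank of GGTGTG was 743, but with a sign turned to fewer at summits it was 960 in the 1396 strongest peaks, 936 in the 2301-peak list, 1007 with merged peaks, and 1027 to 1249 without 1 replicate. The signal difference of peaks with GGTGTGA turned from -11.7 to 15.1 in the strongest peaks, 14.2 in the 3513-peak list and 4.49 with 100 bp windows, and ranged from -55.6 to 36.8 without 1 replicate; none of these passed. Rank correlations of replicates within the strongest peaks were 0.794, 0.777 and 0.829, in a narrower range of signal, which can by itself lower such a correlation. GAGA (0.609 points above flanks) turned to -0.287 in the strongest peaks, -0.218 in the 2301-peak list and -0.707 to -0.518 without 1 replicate, and passed the test at 1.63 in the 3513-peak list, 1.36 with 100 bp windows and 1.04 against shuffled windows. Against shuffled windows the Snail E-box turned to 0.823 points, which did not pass, and the CA repeat to 0.644, which passed (exact sign test, adjusted p = 0.0104). The causes of these changes were not tested. Depth is unknown, so weak regions cannot be called absent.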

Other observations

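Further gene groups were listed after the data were examined, and tested against matched genes with adjustment over these 8 lists alone. Their p-values do not allow for that choice, so they describe the groups and are not counted as calls. Cullins and anaphase-promoting complex genes, which direct protein ubiquitination, had a peak in 8 of 16 members against 2.84 expected (permutation adjusted p = 0.0282), with Cul4, shtd, Cul5 and lmgA the strongest (507, 329, 305 and 294). Subunits of NADH dehydrogenase, the first complex of the respiratory chain, had 13 of 40 against 6.53 expected (permutation adjusted p = 0.0438), led by ND-SGDH, ND-ASHI, ND-24 and ND-B14.5A. Proteasome subunits had 14 of 48 against 7.91 expected (permutation adjusted p = 0.0633), with Prosalpha7 and Prosbeta2 after Rpn6, and exocyst, Sec and Vps proteins 13 of 43 against 7.39 expected (adjusted p = 0.0682). Mediator subunits (6 of 25) and aminoacyl-tRNA synthetases (8 of 33) did not pass (permutation adjusted p = 0.404 for each). Cytochrome P450 genes, which oxidise foreign compounds, had 1 of 81, Cyp6w1, against 13.7 expected (adjusted p = 0.00016, from the smallest p the permutations can give). Serine proteases had 0 of 25 against 4.05 expected (permutation adjusted p = 0.0492). For this list there is a further limit, since 4 genes caught by their symbols alone were taken off it after its result was seen.

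Divergent promoters, with a coding TSS on the other strand within 500 bp upstream, carried peaks more often. Counting each head-to-head group once, 833 of 1837 had a peak (45.3%, interval 43.1 to 47.6%), against 1190 of 10143 other promoters (11.7%, interval 11.1 to 12.4%). The odds ratio was 6.24 (95% interval 5.58 to 6.98), and a divergent group offers a wider window for a peak than a single TSS. Per gene, it was 7.18 (6.41 to 8.04) among promoters without TATCGATA or Motif 1. Genes on the X chromosome had a promoter peak in 550 cases of 2196, an odds ratio against other chromosomes of 1.37 (95% interval 1.23 to 1.52, Fisher's exact test, adjusted p = 6.97e-08). Both per-gene intervals and the Fisher p count genes at a shared promoter apart, so the intervals are too narrow and the p too small.

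Of the tests below, that of TATCGATA against shuffled windows, a background fixed for the T-box sequence, was chosen only after its result was seen, and that within ribosomal protein genes was set after the excess of TATCGATA over all promoters was seen, but before its own result. The first pattern is that peaks lie at promoters. By the rule set beforehand, the result counted against recognition of the T-box sequence by Doc3, the explanation the design names. Promoters with a peak held GGTGTGA within 250 bp of the TSS at an odds ratio of 1.17 (95% interval 0.963 to 1.42) to those without, below the 1.5 set. The interval counts each gene apart, but 1650 of the 2859 genes with a peak had a divergent TSS within 500 bp upstream. Such genes can share a peak and sequence, so the interval is too narrow. Whether its upper limit stays below 1.5 with each divergent group counted once was not tested. The interval also allows a small excess. All promoters with a peak were pooled, so recognition at a few of them, or at peaks outside promoters, could not be seen. The comparison therefore does not decide on this explanation. Core promoter elements read by another protein remain a candidate explanation, since TATCGATA or Motif 1 was held at an odds ratio of 7.85 (7.09 to 8.68). Apart, TATCGATA gave 16.7 (14.6 to 19.0) and Motif 1 gave 1.93 (1.66 to 2.24), so the association is mostly that of TATCGATA. These intervals count genes in the same way. Signal that follows how open a promoter is cannot be told apart from core elements read by another protein. Openness was not measured and no control sample was analysed. Equal signal at every active promoter is argued against below. A promoter peak was held by 46.8% of cytosolic and 37.0% of mitochondrial ribosomal protein genes (Fisher's exact test, p = 0.251), which counted as a fit to signal at any open promoter by the rule set beforehand, but both groups are active in every cell, so the comparison does not decide.

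The second pattern is TATCGATA at peak summits. If every active promoter gave signal alike, ribosomal protein genes with and without the element would have peaks alike. Among these genes, the odds ratio of a promoter peak with the element was 10.7 (95% interval 4.10 to 31.7), and it was 9.71 and 11.0 for cytosolic and mitochondrial members apart, which argues against that explanation. Base composition is also argued against, since the summit share exceeded that of dinucleotide-shuffled windows by 18.2 percentage points. What brings the signal to the element was not tested.

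The third pattern is the weak regions at the Dorsocross genes. Extra copies of the locus from the transgene could raise the number of ranked regions over a wide window. In 80 kb around the genes, the number lay at percentiles 63.0, 90.5 and 70.1 of windows on 3L in replicates 1, 2 and 3, below the 95 that was set beforehand in each. This argues against a copy number large enough to add regions across the window; a smaller inserted segment was not tested.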
